A study of Mus musculus with 6 samples.

How the data were processed

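RNA was extracted with Trizol from primary hindlimb myoblasts, and poly(A) libraries were made from 500 ng with the NEBNext Ultra II kit, per the labels' protocols. The submitters' processing notes name Trim Galore 0.6.6, TopHat2 2.1.1, Partek and the mouse build mm10, with no role or order. The gene annotation and the counting method are not given in the sources used here. The authors deposited a table of RPKM values (reads per kilobase of transcript, scaled to the total reads of the library) for 25220 genes in 6 libraries, which is the measurement used. A second deposited table holds the authors' comparison of the groups on the log2 scale, with p-values and q-values, a ratio and fold change, and means of log2 of RPKM + 0.001, per the file headers; p-values are missing there for 3695 genes. Its group means matched those recomputed from the RPKM values within 5e-05. The authors also deposited tables of enriched terms for the higher and the lower genes, with log10 p and log10 q and counts and percent of genes per term. No column of per-sample values was left unused.

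Depth was estimated from the RPKM table, since 1 read in a gene of known length gives the smallest step. Lengths came from GENCODE M21 for 6134 genes with 1 transcript, on GRCm38, the assembly that mm10 names. Among single-exon genes of up to 20 reads, between 47.2% and 56.1% of values lay within 1% of a whole number of reads at the estimated depth, against a median between 4.1% and 5.6% at other depths. The annotation behind the other values was not known. Since not nearly all values were whole, no count test was run. The level of 3 reads in a transcript of 1 kb was between 0.069 and 0.153 RPKM. Such floors cover counting error only. Samples were placed in their groups from their titles. The labels do not say that the 3 replicates of a group came from separate animals or cultures, so p-values measure only the spread between these samples. That spread is not technical alone, since each group held libraries with Xist and libraries with Y-linked expression and so drew on more than 1 animal. No 2 libraries shared more than 0.005% of values, so none was a copy of another. A second library from the same RNA or culture would not show in this check.

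Genes with a mean of at least 0.5 RPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) on log2 of RPKM + 0.5, with the genotype as the term and no block, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes are on that scale and understate changes of low genes. Set tests used camera with a preset correlation of 0.01 on 36 lists fixed before the data were examined. Of these 35 had members to test. The list of mitochondrially encoded genes had none. Members of a list are counted over all genes tested and also adjusted over the list alone. The named genes followed a rule fixed before the data were examined: the serine synthesis genes, the 12 largest log2 fold changes in each direction with mean RPKM of at least 2 and no overlap of the groups (leaving out unnamed gene models), and up to 3 tested members of each list with the smallest p. Some genes that this rule takes are not reported here. Other names were chosen after their values were seen, among them Igfbp7, Timp1, Lox, Col6a3, Mfap5, Col3a1, Acta2, Myod1, the Cdkn genes and the untested markers. Positions are from RefSeq for GRCm38.p6. Reads of near-identical or overlapping genes could not be told apart.

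On simulated data for Psat1 cKO against Ctrl (12251 genes, 200 changed), the test recovered 74% of genes changed 1.5-fold, 92.8% of those changed 2-fold, 97.6% at 4-fold and 99.6% at 8-fold, and 5.4% of calls were false. Camera called 20 of 20 simulated lists that were shifted and 1 of 20 that were not. Noise was independent between the simulated genes. These simulations therefore do not give the error rate for real lists whose genes move together, such as the sarcomere genes (estimated correlation 0.66). For the closing section, the excess over the control mean of each higher gene with a mean of at least 2 RPKM, and of each called stromal or matrix gene at any level, was compared between every pair of Psat1 cKO libraries, with an expected SD from counting and the spread of the controls, and libraries with 1 fixed added profile were simulated 2000 times. The alternatives were pseudocounts of 0.1 and 1, no filter and a filter at 2 RPKM, TMM scaling, quantile normalization, the replicate number as a block, no variance trend, array quality weights, each library left out in turn, a 1.5-fold threshold, and for lists an estimated correlation and fry. A pseudocount of 0.001, an adjustment for the Xist and Y-linked split and fits within each side of that split were added after the data were seen. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.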

Results

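Poly(A) RNA was measured in primary myoblasts, the muscle precursor cells grown out from satellite cells, taken from mouse hindlimb muscle and kept in a medium with horse serum and basic fibroblast growth factor. Of the 6 libraries, 3 came from control cells with floxed Psat1 alleles and no Cre (Ctrl) and 3 from cells that also carried Cre at 1 Pax7 allele (Psat1 cKO), in which Psat1 is to be deleted. The comparison asked what changed in the transcripts of myoblasts when Psat1, the aminotransferase of the serine synthesis pathway, was targeted. The labels do not say whether this Cre needs to be induced or was induced. Cre was present in Psat1 cKO only, so the comparison covers Cre and the loss of Psat1 together. The steps between the lowest RPKM values put the depth at 33700000, 39500000 and 43300000 reads in the Ctrl libraries and at 35300000, 29000000 and 19600000 reads in the Psat1 cKO libraries, where the third library was the shallowest of all 6. At those depths 1 read in a transcript of 1 kb was worth between 0.0231 and 0.0511 RPKM. Xist was expressed in Ctrl 1, Psat1 cKO 1 and Psat1 cKO 2, while Ddx3y and the other Y-linked genes measured were expressed in Ctrl 2, Ctrl 3 and Psat1 cKO 3, so the groups were not balanced in this respect.

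Psat1 (Entrez 107272, GRCm38 chromosome 19, 15905123 to 15925059) was lower in every Psat1 cKO library than in every control. It stood at 91.8, 93.4 and 100.2 RPKM in the controls and at 63.5, 74.7 and 71.8 RPKM in Psat1 cKO, or 95.1 ± 4.49 against 70.0 ± 5.81 RPKM (SD, n = 3 each), so that 73.6% of the control level remained. The log2 fold change was -0.44 with a standard error of 0.07 (limma, adjusted p = 0.0225). The values are for the whole gene and do not show which exons were read, so they do not separate deleted from intact transcripts. The other enzymes of the pathway were close to their control level: Phgdh, which takes the first step from 3-phosphoglycerate, had a log2 fold change of -0.04 (adjusted p = 0.798), and Psph, which takes the last step, of -0.14 (adjusted p = 0.241). Of the 3 serine synthesis genes 1 was called over all genes tested, and 2 were lower when adjusted over the list alone. The Psat1 call was lost in 5 of the 6 fits that left out 1 library, all except that without Psat1 cKO 1, with adjusted p between 0.0517 and 0.0834 in those 5, while the log2 fold change stayed between -0.49 and -0.40.

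**Figure D1:**
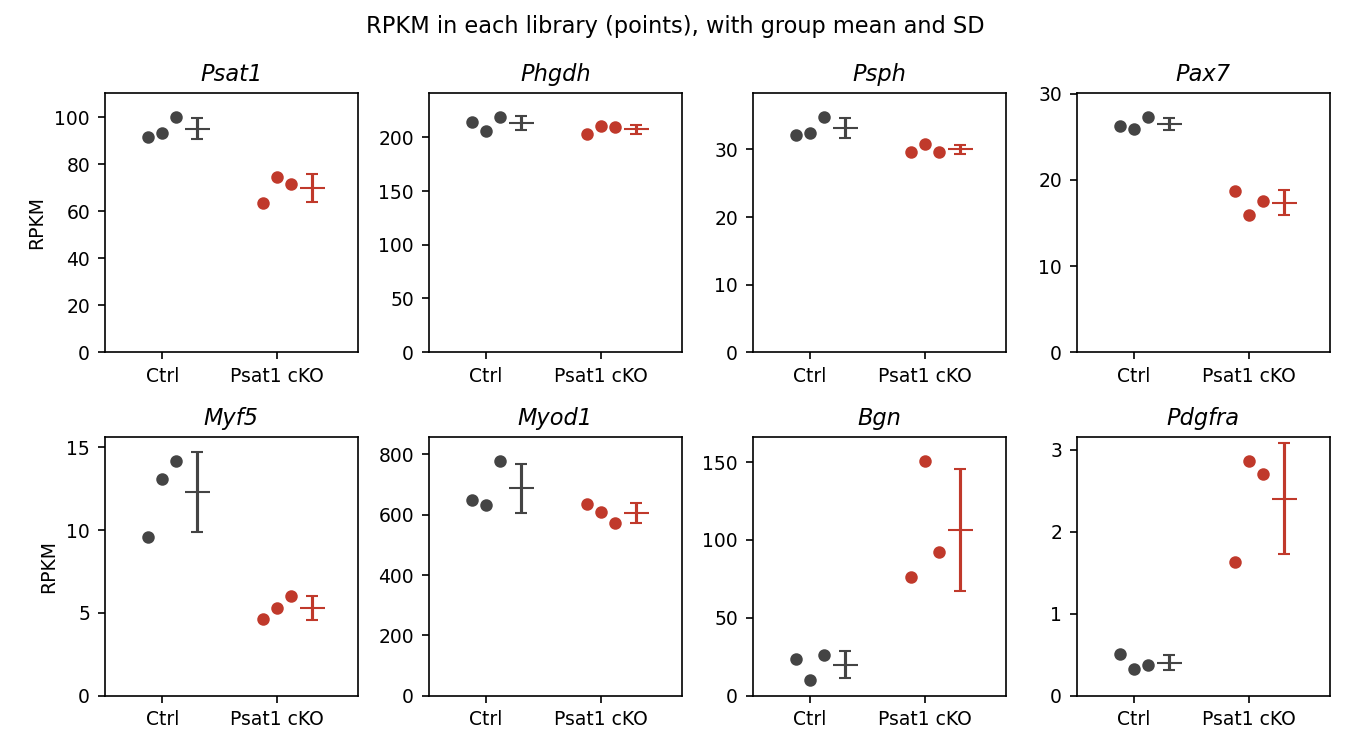
RPKM of 8 genes in the 3 Ctrl and 3 Psat1 cKO libraries; points are libraries and the bars beside them give the group mean and SD, on axes that start at 0. Psat1, Pax7 and Myf5 lie lower in all Psat1 cKO libraries, Bgn and Pdgfra lie higher, and Phgdh lies between 203 and 219 RPKM in all 6.

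Across the transcriptome, 220 genes were higher and 60 lower in Psat1 cKO among 12251 tested (limma, adjusted p under 0.05), and 81 of the higher and 6 of the lower genes differed by at least 2-fold. At an unadjusted p under 0.05 there were 926 higher and 836 lower genes. The values of the groups did not overlap for any of the 280 called genes. The same held for 20.5% of all genes tested, where chance gives 10%. The first principal component held 45.5% of the variance and parted the groups. Leaving out any library except Psat1 cKO 1 (167 higher and 55 lower) moved a count by over 1.5 times: without Ctrl 1 there were 173 higher and 29 lower, without Ctrl 2 54 and 12, without Ctrl 3 122 and 37, without Psat1 cKO 2 49 and 12, and without Psat1 cKO 3 106 and 35. Without the filter on low values, which raised the genes tested to 20767, only 1 gene was higher and 3 were lower.

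**Figure D2:**
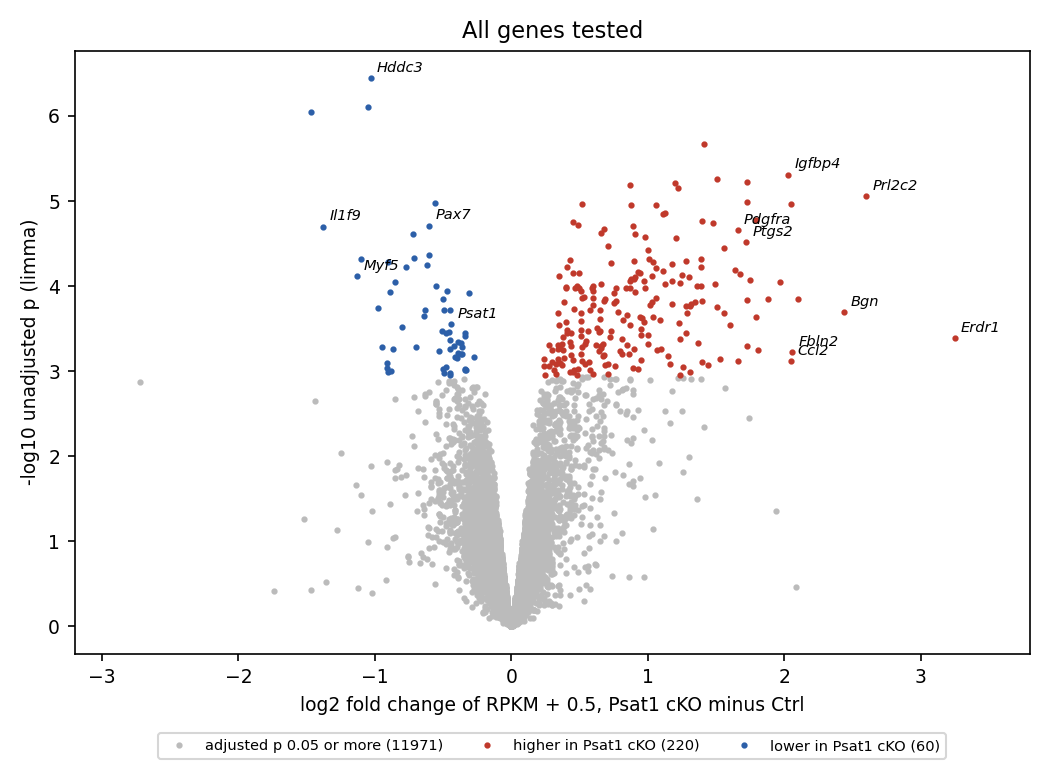
Log2 fold change (Psat1 cKO minus Ctrl, on log2 of RPKM + 0.5) against the unadjusted p of limma on a -log10 axis, 1 point for each of the 12251 genes tested. Red points are the 220 genes called higher, blue points the 60 called lower, and grey points those with adjusted p of 0.05 or more.

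The genes that rose most included several secreted and matrix proteins. Bgn, which encodes the matrix proteoglycan biglycan, rose from 19.9 ± 8.60 to 106 ± 39.1 RPKM, a log2 fold change of 2.44 with a standard error of 0.37 (adjusted p = 0.0185). Fbln2, for the matrix protein fibulin-2, rose from 21.8 ± 11.4 to 87.7 ± 30.9 RPKM, and Col1a2, for a chain of type I collagen, from 5.41 ± 2.01 to 20.3 ± 7.82 RPKM. Igfbp4, a binding protein of insulin-like growth factors, rose from 5.81 ± 1.46 to 25.0 ± 4.0 RPKM (log2 fold change 2.03, standard error 0.18, adjusted p = 0.00807), and Inhba, for the activin A subunit, from 5.03 ± 1.98 to 20.2 ± 3.25 RPKM. The chemokine gene Ccl2, the protease inhibitor gene Serpinb2 and the annexin gene Anxa3 had log2 fold changes of 2.05, 1.88 and 1.79. Igfbp4 kept its call whichever library was left out. The highest adjusted p without 1 library was 0.109 for Ccl2 (without Psat1 cKO 2), 0.106 for Fbln2 (without Ctrl 3), 0.0941 for Col1a2 (without Psat1 cKO 3), 0.0738 for Anxa3, 0.0606 for Bgn and 0.055 for Inhba (each without Psat1 cKO 2), and 0.0703 for Serpinb2 (without Ctrl 2). Erdr1 had the largest log2 fold change, 3.25, but lies in a repeated stretch at the end of chromosome X (170010526 to 170018797) and read 8.39 RPKM in Ctrl 1 against 40.5 and 42.3 in the other controls, and the prolactin family genes Prl2c2 (2.60) and Prl2c3 (2.1) are near-identical copies, so these 3 values are uncertain.

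Fewer genes fell, and by less. Myf5, a myogenic transcription factor (Entrez 17877, chromosome 10, 107482908 to 107486927), fell from 12.3 ± 2.43 to 5.30 ± 0.707 RPKM, a log2 fold change of -1.13 with a standard error of 0.15 (adjusted p = 0.0138, 0.056 without Ctrl 2 and 0.0523 without Psat1 cKO 2). Hddc3 (chromosome 7, 80343075 to 80346716) fell from 24.6 ± 0.650 to 11.9 ± 0.951 RPKM, with a log2 fold change of -1.03 (adjusted p = 0.00370). Among called genes with a mean of at least 2 RPKM, the interleukin-1 family gene Il1f9 had the largest fall, -1.38, followed after Myf5 by Tceal5 at -1.05, while the pseudogene Morf4l1-ps1, at 1.26 RPKM in controls, had -1.47. Stac2, Dynap, Capn6, Tnfrsf1b, Cdsn, Cdh6, Cpt1b and Nnt followed, with log2 fold changes between -0.98 and -0.85. Nnt encodes the mitochondrial transhydrogenase that makes NADPH, and went from 18.1 ± 2.78 to 9.76 ± 0.806 RPKM. Il1f9, Tceal5, Hddc3 and Tnfrsf1b kept their call whichever library was left out. Without Ctrl 2 the adjusted p was 0.0731 for Stac2, 0.114 for Dynap, 0.156 for Capn6, 0.0545 for Cdh6, 0.0997 for Cpt1b and 0.0551 for Nnt, and without Ctrl 1 it was 0.151 for Cdsn.

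Among the satellite cell and myoblast regulators, 2 of 18 tested genes fell, over all genes and adjusted over the list alone. Pax7, the transcription factor that marks satellite cells and the locus of the Cre allele (Entrez 18509, chromosome 4, 139737059 to 139833530), fell from 26.5 ± 0.685 to 17.4 ± 1.39 RPKM, a log2 fold change of -0.60 with a standard error of 0.06 (adjusted p = 0.00907), whichever library was left out. Myf5, above, was the other. Myod1 stood at 687 ± 80.5 RPKM in controls and 606 ± 32.3 in Psat1 cKO (log2 fold change -0.18, adjusted p = 0.445). None of the 29 muscle differentiation and sarcomere genes passed the test, over all genes or adjusted over the list alone, although all 29 had a negative log2 fold change, with a median of -0.40 (-0.19 without Psat1 cKO 3 and -0.26 without Ctrl 2). Ckm, for muscle creatine kinase, was at -0.63 (adjusted p = 0.0658), Tnnt3 at -0.49 (adjusted p = 0.185) and Actc1 at -0.49 (adjusted p = 0.252). Of 17 alternatives, Ckm passed in 2, Tnnt3 in 1 and Actc1 in 0. As lists, both were called lower by camera with a preset correlation (adjusted p = 0.0108 for the regulators and 2.50e-08 for the sarcomere genes) and neither with an estimated correlation (adjusted p = 0.525 and adjusted p = 0.494). The call of the regulators was also lost without Ctrl 3 (adjusted p = 0.139) and without Psat1 cKO 3 (adjusted p = 0.101).

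In the secretion, NF-kB, matrix and TGF-beta lists, between 2 and 9 genes of each rose and 0 fell over all genes tested. In the list of senescence-associated secretion and cell cycle inhibitors, 9 of 16 tested genes rose, and 11 when adjusted over the list alone. Those that rose were secreted factors, among them Igfbp4, Cxcl1 (log2 fold change 1.39), Igfbp5 (0.52), Igfbp7 (1.66) and Timp1 (0.66), while the inhibitors themselves did not pass the test, with log2 fold changes of -0.09 for Cdkn1a, 0.04 for Cdkn2a and -0.07 for Cdkn2b. Of 11 NF-kB targets and chemokines 4 rose (7 adjusted over the list alone), namely Ptgs2, the inducible prostaglandin synthase, from 11.2 ± 3.03 to 37.7 ± 7.39 RPKM, and Cxcl1, Lif and Ccl2. Of 24 extracellular matrix genes 5 rose (8 adjusted over the list alone), namely Bgn, Col1a2, Nid1 (1.49), Lox (1.44) and Col6a3 (0.95), while Col3a1 stood at 41.0 and 39.0 RPKM. Of 13 TGF-beta targets 2 rose, among them Ccn2 (1.28), and when adjusted over the list alone 6 were higher and 1 lower. Adjusted over the lists, camera with a preset correlation gave p = 1.32e-09 for the secretion list, 2.1e-08 for the NF-kB list, 2.33e-08 for the matrix list and 0.000512 for the TGF-beta list. With an estimated correlation none was called, at adjusted p = 0.25, adjusted p = 0.25, adjusted p = 0.494 and adjusted p = 0.344. Ptgs2 kept its call whichever library was left out, while the highest adjusted p was 0.0545 for Cxcl1, 0.0709 for Igfbp5, 0.129 for Timp1, 0.0819 for Lif, 0.0593 for Nid1, 0.123 for Lox and 0.109 for Col6a3 (each without Ctrl 2), and 0.128 for Igfbp7 and 0.0851 for Ccn2 (both without Psat1 cKO 2).

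Some markers of stromal and smooth muscle cells rose in the same libraries, and those of 4 other cell types did not pass the test. Of the 8 fibro-adipogenic progenitor markers tested, genes of the muscle's resident stromal cells, 4 rose (7 adjusted over the list alone). Pdgfra rose from 0.404 ± 0.0947 to 2.40 ± 0.672 RPKM, whichever library was left out, Cd34 from 6.13 ± 1.24 to 16.6 ± 4.45, Smoc2 from 1.37 ± 0.262 to 5.42 ± 2.36 and Mfap5 from 0.875 to 2.77. All 8 had positive log2 fold changes. The other members of that list were below the filter, with Ly6c1 at no more than 0.472 RPKM, Apod at no more than 0.434, Lum at no more than 0.123, Dpt at no more than 0.0299 and Pi16 at no more than 0.0126 in any library. Of 8 smooth muscle and pericyte markers 2 rose (4 adjusted over the list alone), Mcam (1.01) and Tagln (1.53), while Acta2 stood at 198 and 214 RPKM. The highest adjusted p without 1 library was 0.0523 for Cd34, 0.0943 for Smoc2 and 0.169 for Mfap5 (each without Ctrl 2) and 0.0517 for Mcam and 0.121 for Tagln (both without Psat1 cKO 2). No endothelial, immune, adipocyte or Schwann cell marker was called by limma among the 5, 3, 3 and 3 tested. The medians of these lists were 0.25, 0.27, 0.26 and 0.28, and the endothelial median ran from -0.22 to 0.45 over the alternatives. All 5 endothelial and all 3 Schwann cell markers had positive log2 fold changes, with Cdh5 at 0.80 (adjusted p = 0.0845), while 2 of 3 immune and 2 of 3 adipocyte markers did, with Laptm5 at -0.44 and Pparg at -0.27. Adjusted over the list alone, 1 endothelial marker was higher. The stromal list was called by camera with a preset correlation (adjusted p = 1.60e-08) and so was the smooth muscle list (adjusted p = 0.00485), and neither with an estimated correlation (adjusted p = 0.212 and adjusted p = 0.344). Of the 15 lists called with the preset correlation, fry's directional test called the stromal, secretion and NF-kB lists (adjusted p = 0.0286, 0.0286 and 0.032).

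**Figure D3:**
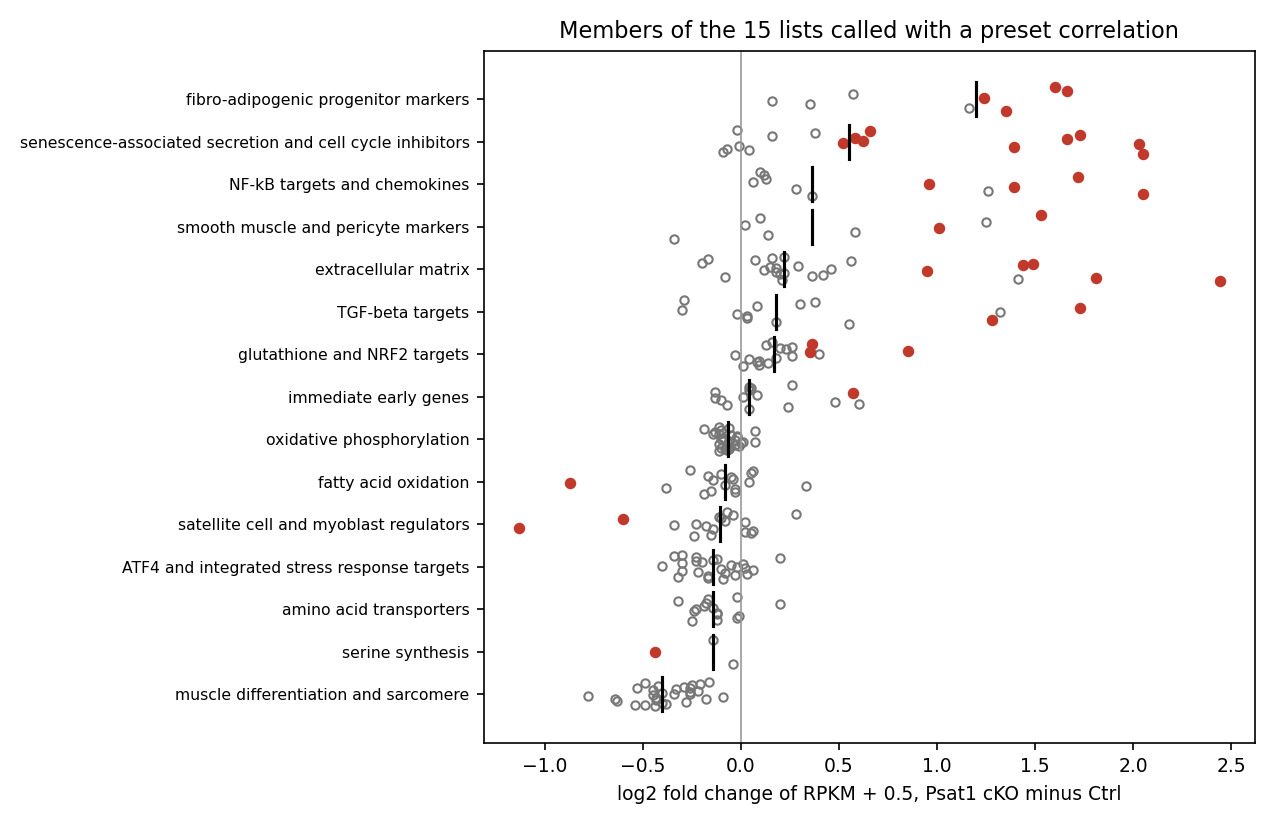
Log2 fold change (Psat1 cKO minus Ctrl, on log2 of RPKM + 0.5) of the tested members of the 15 lists called by camera with a preset correlation; filled red points passed the test over all genes, open points did not, and the black bar is the list's median. The medians run from -0.40 for the sarcomere genes to 1.20 for the fibro-adipogenic progenitor markers.

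Metabolic and stress lists moved little. Of 18 glutathione and NRF2 targets 3 rose, both over all genes and adjusted over the list alone: Me1 (log2 fold change 0.35), Nqo1 (0.85) and Tkt (0.36), the first and last of which encode NADPH metabolism and pentose phosphate enzymes. None of the 25 ATF4 and integrated stress response targets passed the test by either adjustment, with Trib3 at -0.34 (adjusted p = 0.0779), Atf3 at -0.32 and Pck2 at -0.30, nor did any of the 15 amino acid transporters or the 28 oxidative phosphorylation genes, whose medians were -0.14, -0.14 and -0.07. Of 17 fatty acid oxidation genes Cpt1b alone fell, at -0.87, and adjusted over the list alone 2 were lower and 1 higher. Of 15 immediate early genes Ier3 alone rose, at 0.57, with 5 higher adjusted over the list alone. The highest adjusted p without 1 library was 0.0595 for Me1, 0.16 for Tkt, 0.0997 for Cpt1b and 0.16 for Ier3 (each without Ctrl 2) and 0.104 for Nqo1 (without Psat1 cKO 2). These 6 lists, and the serine synthesis list, were called by camera with a preset correlation. With an estimated correlation none was, at adjusted p = 0.344 for the glutathione and immediate early lists and adjusted p = 0.494 for the ATF4, transporter, oxidative phosphorylation, fatty acid and serine synthesis lists.

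The remaining 20 lists tested were not called in the main fit, though some gained a call under alternatives. Their medians lay between -0.08 and 0.28, and they included the genes of DNA replication (0 of 27 called, median -0.04), of G2 and mitosis (0 of 24, median -0.03), of nucleotide synthesis (0 of 23, median 0.02) and of folate one-carbon and glycine metabolism (0 of 21, median -0.02, with Aldh1l2 lowest in p at -0.29 and adjusted p = 0.0779). Single members of 3 such lists were called: the p53 target Gadd45a at -0.34, the cholesterol synthesis gene Nsdhl at -0.55 and Dkk2, of the Wnt list, at 1.23. The Gadd45a call was lost in all 6 fits that left out 1 library, and without Ctrl 2 the adjusted p was 0.172 for Gadd45a, 0.0595 for Nsdhl and 0.0927 for Dkk2.

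The authors' deposited table, whose group means are of log2 of RPKM + 0.001, listed 81 genes higher and 34 lower at q under 0.05. Of those 115, 93 passed the filter and 80 were also called here. The model behind its p-values is not known here. Of the 280 genes called here, the other calls did not reach that q, among them Cxcl1 (q = 0.660 in the authors' comparison). The authors' deposited table of enriched terms for higher genes was led by extracellular matrix organization (log10 p = -19.39) and positive regulation of cell migration (log10 p = -17.77). That for lower genes was led by heterophilic cell-cell adhesion (log10 p = -5.07, log10 q = -0.8). The symbols in these deposited tables had q up to 0.426 and 0.435 in the authors' deposited comparison, with fold changes of at least 1.51 and 1.52 in size.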

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

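The adjustment for the Xist and Y-linked split, the fits within each side of it and the pseudocount of 0.001 were chosen after the data were seen. The counts of 220 higher and 60 lower genes stayed within 1.5 times under pseudocounts of 0.1, 1 and 0.001, a filter at 2 RPKM, TMM, quantile normalization, no variance trend, array weights and the adjustment for the split. Without a filter they were 1 and 3: that tested 20767 genes in place of 12251, and the prior degrees of freedom went from 3.72 to 1.35. At least 1.5-fold, 26 genes were lower. Leaving out 1 library gave 49 to 173 higher and 12 to 55 lower genes, lowest without Psat1 cKO 2 (49 and 12) and Ctrl 2 (54 and 12), with 122 and 37 without Ctrl 3, 106 and 35 without Psat1 cKO 3 and 29 lower without Ctrl 1; fewer samples entered these fits. The libraries with Xist (Ctrl 1 against Psat1 cKO 1 and 2) gave 46 and 26 and those with Y-linked expression (Ctrl 2 and 3 against Psat1 cKO 3) 42 and 14; each fit has 1 library in an arm, which is assumed to vary like the other arm. With the replicate number as a block there were 200 higher and 121 lower genes, and 16 lists; the numbers are not said to pair samples, same-numbered libraries deviated with r = 0.20, -0.03 and 0.17 across genes (which are not independent), and not every library correlated best with its own number. Lists called numbered 12 to 17 when 1 library was left out, 0 with an estimated correlation, 3 by fry's directional test and 18 by its mixed test. Of the 45 named genes that were called, 10 kept the call whichever library was left out, 35 lost it without at least 1, and 44 lost it without the filter; of the 15 lists, 10 kept the call whichever library was left out. Those that lost it were serine synthesis (highest adjusted p = 0.0599) and amino acid transporters (0.0675), both without Ctrl 3, myoblast regulators (0.139, without Ctrl 3), fatty acid oxidation (0.0867) and immediate early genes (0.131), both without Ctrl 1. Some lists not called in the main fit gained a call under alternatives. Ribosomal proteins did so in 8 of 19, and Schwann cell markers and demethylases in 2 each. DNA replication, G2 and mitosis, endothelial markers, interferon response and autophagy did so in 1 each. Reversals were confined to uncalled results, and their cause was not tested. When 1 library was left out, the log2 fold change of Emcn ran from -0.24 to 0.87 and that of Fabp4 from 0 to 1.34, both lowest without Psat1 cKO 3, and the lists whose direction turned had medians from -0.02 to 0.04 for nucleotide synthesis, -0.05 to 0 for G2 and mitosis, -0.05 to 0.01 for p53 targets, 0.14 to 0.47 for immune markers, 0 to 0.38 for adipocyte markers, -0.01 to 0.09 for ribosomal proteins, -0.12 to -0.03 for Wnt targets and -0.1 to 0 for demethylases. The list direction also turned for nucleotide synthesis (median 0) and Wnt targets (-0.07) with array weights, for adipocyte markers (0) and Wnt targets (-0.02) without a filter, for immune markers (0.26) with the 2 RPKM filter, and for nucleotide synthesis (0.02) and Wnt targets (-0.08) with fry. Psat1 cKO 3 had the fewest reads, 19600000, where 3 reads in a transcript of 1 kb make 0.153 RPKM.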

Other observations

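Some called genes outside the fixed lists were chosen after their values were seen, and no list or enrichment test covers them, so they stand for themselves and not for a group. The phospholipase gene Pla2g4a rose from 5.16 ± 1.39 to 15 ± 1.16 RPKM (log2 fold change 1.48), the prostaglandin E synthase gene Ptges from 1.34 to 3.31 RPKM (1.04), the lipoxygenase gene Alox5 from 13.5 to 30.4 RPKM (1.13), the transporter gene Slco2a1 by a log2 fold change of 1.56 and the prostacyclin receptor gene Ptgir by 0.87. Of genes for secreted signals, log2 fold changes were 1.73 for Fgf2, 1.28 for Fgf7, 0.77 for Bdnf, 0.76 for Kitl and 1.41 for Wnt5a, which were called, and 0.38 for Tgfb1 and -0.02 for Vegfa, which were not (adjusted p = 0.0523 and 0.943 by limma). Of transcription factor genes, Twist1 (1.73), Twist2 (1.00), Tbx18 (0.87), Pitx1 (0.82), Ebf1 (0.87) and Ebf2 (0.86) rose, while Snai2 fell (-0.27). Pitx1 and Ebf2 stayed low, going from 0.257 to 0.845 RPKM and from 0.229 to 0.825 RPKM. Both reached the filter in only 4 of the fits that left out 1 library, and lost the call in 4 and 3 of those. Of these 17 called genes, 4 kept the call whichever library was left out (Pla2g4a, Fgf2, Wnt5a and Twist1), and the highest adjusted p by limma without 1 library was 0.164, for Kitl without Ctrl 2. None of 20 Hox genes tested by limma was called, with log2 fold changes between -0.45 and 0.18.

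Every test of an explanation given here was chosen after the result it concerns was seen. As to chance, 1 of the 10 splits of the 6 libraries, the real one, gave 220 higher genes, and the highest other split gave 4. It was likewise 1 for the 60 lower genes, where the highest other gave 3. For lists, 2 splits gave as many as the real 15, the other being that of Ctrl 1, Ctrl 2 and Psat1 cKO 1 against the rest, with 16. Every split other than the real one called lists, between 3 and 16 of them. Camera with the preset correlation thus called lists for arbitrary groupings too, and its p-values are not to be taken at face value. With 10 splits no share under 0.05 can be reached.

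The first pattern is that genes of the matrix, stromal and secretion lists rose while Pax7 and Myf5 fell. An unequal number of Xist and Y-linked libraries is argued against as its whole cause. No called gene overlapped between the groups, which a change that follows that split alone would not give. A call itself selects for groups that do not overlap, so this was largely set by the choice of genes. Grouping the libraries by Xist and Y-linked expression gave 7 called genes, against 280 for the real groups. After adjusting for the split the higher genes kept a median of 97% of their log2 change, and 144 of 220 kept their call. As these genes were chosen for a group difference, a high share kept was largely set by that choice. A lower share of myogenic cells is argued against as the whole source of the lower Pax7 and Myf5. The median of 15 other myoblast regulators was -0.10, against -0.60 for Pax7. Only regulators in a list of another cell type were left out of the 15, so some may be expressed in other cells too. All 29 sarcomere genes were negative, however, with a median of -0.40 (-0.19 without Psat1 cKO 3), which leaves a smaller loss of myogenic cells open. These genes moved together (estimated correlation 0.66), and their mean log2 level overlapped between the groups, at 6.7 in Ctrl 3 and 6.81 in Psat1 cKO 2. Lower levels of these genes within myogenic cells would give the same sign, so their fall does not measure the share of such cells. A non-myogenic cell type of fixed profile, at a different share in each Psat1 cKO library, stays a candidate for most higher genes outside the stromal and matrix lists. Of 152 with a mean of at least 2 RPKM, at most 9 (5.9%) departed from 1 common ratio of the excess in any pair. A departure was over 2 expected SD, whose median was between 0.44 and 0.5 log2, so the test was weak for most genes. The 9 for Psat1 cKO 3 over Psat1 cKO 1 included Prl2c2, Nqo1 and Igfbp5, at 7.32, 3.55 and -3.85 expected SD. With stromal and matrix genes included, 15 of 158 (9.5%) departed for Psat1 cKO 3 over Psat1 cKO 2, where 200 simulations gave up to 11.6%. A shared program in the myoblasts would give 1 common ratio too, as would such cells. Whether the same cells brought the called stromal and matrix genes cannot be told apart from a separate change of these genes: 6 of 9 departed from that ratio in each pair with Psat1 cKO 2 and 0 of 9 for Psat1 cKO 3 over Psat1 cKO 1, Cd34 and Smoc2 in opposite directions, a count that 0 of 2000 simulations of a fixed profile reached where noise was independent between genes and 110 of 2000 where it moved these genes together. All 8 stromal markers tested had positive log2 fold changes, with a median of 1.20, and the list median lay between 0.20 and 1.56 over the alternatives. The filter takes the mean of all 6 libraries, so a rise itself helps a marker to be tested. The 8 others stayed at or under 0.472 RPKM in every library. Col3a1, chosen after its values were seen, stood at 41.0 and 39.0 RPKM. An effect of Psat1 loss, of Cre or of the Cre insertion on Pax7 itself was not tested, as all 3 come with the group.

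The second pattern is that called genes gathered on chromosome 7. The densest window of 10 Mb, from 95000001 to 105000000, held 9 called genes of 71 tested where 1.61 were expected (genome-wide permutation p = 0.0035), and from 80000001 to 105000000, which joins the windows with a genome-wide p under 0.1, 17 of 138 genes were called, 8 higher and 9 lower, among them Hddc3, Fah, Folr1 and Relt. A chromosome segment of another strain origin that differs between the groups may account for these genes, but no sequence was used here. DNA that flanks the Cre insertion at Pax7 cannot be told apart from chance as a source of the 9 called genes within 10 Mb of Pax7, of 197 tested and 4.48 expected (exact one-sided hypergeometric test, p = 0.036), since the nearest 5 Mb held 2 of 84 where 1.91 were expected (exact one-sided p = 0.572). On chromosome 13, from 10000001 to 20000000, 5 of 30 genes were called where 0.68 were expected (genome-wide permutation p = 0.1). Inhba, Nid1 and the near-identical Prl2c2 and Prl2c3 lie there. Prl2c4 was placed at the same position as Prl2c3 (12790816 to 12800093), so that locus was counted more than once. Genotypes of the mice along chromosome 7 would decide whether Hddc3 and its neighbours belong to the effect of Psat1.

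The third pattern is that 73.6% of the control Psat1 level remained, between 66.8% and 78.6% per library. An exchange of libraries between the groups is argued against, as 0 Psat1 cKO libraries reached the lowest control. Alleles or cells that escaped recombination may account for the rest, also if Cre was not or not fully induced, on which the labels say nothing, but the same 73.6% would follow if recombined alleles still made a transcript that is counted, and these cannot be told apart from values for the whole gene. If escape is the cause, the differences from control would be diluted by unrecombined cells.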
